A study of Homo sapiens with 15 samples.

How the data were processed

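RNA-seq and ATAC-seq were made from MCF-7 cells, an estrogen-receptor-positive human breast cancer line. Per the labels' protocols, cells were kept for 3 days in medium with 5% charcoal-dextran-stripped serum and then received ethanol vehicle or 0.1 nM 17-beta-estradiol (E2). RNA was taken from 3 ethanol and 3 E2 cultures at 3 h. Chromatin was taken from 3 ethanol cultures, 3 cultures at 1 h and 3 at 3 h of E2, with 50000 cells per ATAC reaction. ATAC-seq uses a transposase to cut and tag open chromatin, so the count over a region measures its accessibility. The 15 libraries formed 5 groups, taken from the titles of the samples. The labels state biological replicates. The p-values measure the spread between these libraries.

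The RNA table holds whole-number counts per gene for 13671 genes, as deposited by the authors, and the ATAC table holds whole-number counts per region for 204297 regions, as deposited by the authors. Per the submitters' processing notes, Trim Galore 0.4.3, STAR, featureCounts and edgeR were used for RNA, and Trim Galore 0.4.3, Bowtie2, Picard, MACS2, featureCounts and edgeR for ATAC, on genome build hg19. Whether regions were called per library or on pooled libraries, whether fragment ends were shifted for the transposase, the strand setting of the RNA counts and the filter on low counts are not given in the sources used here. The smallest summed count was 51 for a gene and 220 for a region. The deposited tables also hold the authors' log2 CPM and log2 fold changes, and the authors' p-values and false discovery rates. These columns were used only for the comparison of calls with the authors' deposited table. The ATAC table assigns a gene to each region. That assignment appeared to take the lower coordinate of a gene as its start on both strands. The authors' distance was 0 for 8322 regions assigned to plus-strand genes but for 921 assigned to minus-strand genes. The first coordinate of the listed gene location matched the lower end of the gene for 81.9% of 6375 positions on the minus strand and 70.7% of 8192 on the plus strand. A listed span would begin there on either strand, so this match alone does not show how distances were taken. With the nearest strand-aware 5' end among the genes of the RNA table, 33.5% of regions kept the same gene, a change of both the strand rule and the set of genes. The authors' assignment was kept for the planned tests, a strand-aware assignment was added as an alternative after this was seen, and every distance printed is from the region to the strand-aware 5' end of the assigned gene. Positions are hg19, counted from 1. Exon, intron and 5' end come from the gene coordinates in the RNA table. Gene symbols are those of the tables.

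Total counts were 26.2, 34.1 and 25.6 M counts in RNA ethanol replicates 1 to 3 and 27.0, 26.8 and 30.6 M in RNA E2 replicates 1 to 3. ATAC totals were 34.6, 44.8 and 36.3 M for ethanol, 18.6, 26.6 and 20.1 M for 1 h and 18.5, 24.5 and 24.6 M for 3 h. Replicates of 1 group correlated at 0.992 to 0.996 (RNA) and 0.896 to 0.953 (ATAC) on the log scale. Their counts differed by more than sampling noise in every pair (chi-square per degree of freedom 3.51 to 14.7 for RNA and 2.89 to 10.2 for ATAC), so each library counted as 1 replicate.

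Both tables were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05). The filter removed no gene and no region. RNA used its 6 libraries and ATAC all 9 in a common fit with contrasts for 1 h and 3 h against ethanol and for 3 h against 1 h. Levels are CPM, counts per M (mega) of TMM-scaled library size, given as mean ± SD of 3 libraries. The standard error of a log2 fold change is its size divided by the square root of F, written as log2 value ± SE. Exact and permutation tests were two-sided.

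Of 21 gene lists written from textbook knowledge before the data were examined, 20 had 5 or more measured members and were tested with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation as the alternative), adjusted over lists. The lists were estradiol-induced, estradiol-repressed, immediate early, G1/S and replication, G2/M and mitosis, ribosome biogenesis, endoplasmic reticulum stress and amino acid response, estrogen receptor cofactors, luminal identity, basal and mesenchymal markers, fibroblast, endothelial and immune markers, TGF-beta and BMP, apoptosis, aryl hydrocarbon receptor targets, sterol and lipid synthesis, interferon response, hypoxia and glycolysis, growth factor signalling, core histones, reference genes and genes of the mitochondrial genome. The design, the alternatives and the rule for named genes were also fixed before the data were examined.

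Shares of raised, lowered and uncalled genes with an assigned region called up or down were compared by Fisher's exact test with 95% intervals. A matched permutation test (100000 resamples) shuffled labels among class and uncalled genes within the same 10 bins of expression and of number of regions. Its mean share therefore includes the class genes. Fold changes of the assays were correlated across genes with intervals from 10000 bootstrap draws. Agreement of the 1 h and 3 h changes was set beside 10 simulations in which all groups, the shared controls included, were drawn unchanged at the fitted spread. Basal accessibility, as log2 of CPM plus 1, used 100000-resample permutations within 10 bins of expression. Genes are not independent replicates, so p-values over genes describe these libraries only.

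Named RNA genes were the 8 largest rises and 8 largest falls among genes with an edgeR adjusted p under 0.05, a mean of 1 CPM or more and no overlap between groups, up to 3 called members of lowest p in each list, and always TFF1, GREB1, PGR, MYC, CCND1 and ESR1. Named regions were, per contrast with ethanol, the 5 largest rises and 5 largest falls under the same conditions, the region of lowest p at 3 h for the 6 fixed genes and the largest RNA changes, the 3 largest rises and falls between the times, and up to 8 genes called in RNA with the lowest ATAC p.

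On simulated data with 200 features changed in each assay, the RNA test on 13658 genes recovered 71.6% of planted changes of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold, with 10 false calls among 187. The ATAC test of 3 h against ethanol on 204297 regions recovered 2.99%, 38.8% and 95.5%, with 5 false calls among 96. A change under 2-fold in a region was therefore often not detected in this simulation, with 200 changed regions, these depths, 3 libraries per group and this spread. These were not varied apart, and the adjusted p also depends on how many regions change.

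Alternatives were relative log expression size factors, library size only, DESeq2 1.42.0, limma-voom, no filter, a mean CPM of 1 or more, other thresholds, only the 6 libraries compared, leaving out each library, the replicate number as a block, other windows for assigning regions and other region summaries. Added after the data were seen were offsets that follow mean accessibility (a loess curve), thinning to the smallest total, the strand-aware assignment, plus-strand genes only, a few of these at 1 h, and more settings for the 3 h against 1 h contrast. Motif content of regions was not analysed here because no hg19 sequence was used. Files were handled with GenomicRanges 1.54.1 and data.table (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.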

Results

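MCF-7 cells were deprived of hormone and then given 0.1 nM E2, the ligand of the estrogen receptor, or ethanol. The series asks, by its title, how chromatin accessibility relates to E2-regulated expression. RNA-seq covered ethanol and 3 h of E2, and ATAC-seq covered ethanol, 1 h and 3 h of E2, with 3 libraries in each of the 5 groups. RNA totals lay between 25.6 and 34.1 M counts. ATAC totals lay between 34.6 and 44.8 M in ethanol and between 18.5 and 26.6 M in the E2 groups, so every E2 ATAC library was shallower than every ethanol ATAC library.

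After 3 h of E2, RNA of the known estrogen receptor targets rose. PGR, the progesterone receptor, rose 13.6-fold, from 4.99 ± 1.88 to 67.1 ± 5.43 CPM (SD, n = 3). GREB1, an estrogen receptor cofactor, rose 6.16-fold, from 198 ± 31.2 to 1217 ± 31.2 CPM, and TFF1, a secreted trefoil peptide, rose 2.76-fold, from 647 ± 102 to 1786 ± 136 CPM. The growth genes MYC, a transcription factor, and CCND1, which encodes cyclin D1, rose 3.00-fold and 2.32-fold. ESR1, which encodes estrogen receptor alpha itself, was 2.59-fold lower, with 594 ± 14.1 CPM in ethanol and 229 ± 7.80 CPM in E2. The log2 fold changes were 3.77 ± 0.17 for PGR, 2.62 ± 0.09 for GREB1, 1.47 ± 0.10 for TFF1, 1.58 ± 0.06 for MYC, 1.21 ± 0.05 for CCND1 and -1.37 ± 0.05 for ESR1, with edgeR adjusted p-values from 4.23e-09 (GREB1 and ESR1) to 1.65e-07 (TFF1).

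The largest rises were in genes with little RNA in ethanol. TGM2, a transglutaminase, rose 21.1-fold, from 1.86 ± 1.34 to 38.3 ± 2.59 CPM, LOXL4, a lysyl oxidase, rose 15.6-fold and VWF, the von Willebrand factor, rose 14.1-fold. HCK, a kinase of the SRC family, rose 16.2-fold, SEMA3G, a semaphorin, 23.7-fold and MGAT3, a glycosyltransferase, 26.5-fold. CYP24A1, the vitamin D 24-hydroxylase, had 1, 0 and 5 counts in the ethanol libraries and 64, 55 and 76 in E2 (log2 fold change 5.01 ± 0.50). TFF2 had 3, 2 and 1 counts in ethanol and 53, 62 and 71 in E2 (4.95 ± 0.38), so the size of these rises rests on few ethanol counts. Ethanol counts were also few for MGAT3 (3, 2 and 19), SEMA3G (3, 4 and 16), HCK (7, 18 and 32) and TGM2 (22, 48 and 88). Without ethanol replicate 3 the log2 fold changes were 6.84 for CYP24A1, 6.44 for MGAT3, 5.75 for SEMA3G, 4.71 for HCK and 5.08 for TGM2, against 5.01, 4.73, 4.57, 4.02 and 4.40 with all libraries, and without ethanol replicate 2 they were 4.32 for CYP24A1 and 4.14 for MGAT3. Among the falls, NXPH1, a neurexophilin, was 12.5-fold lower, BLNK, a B-cell adaptor protein, 7.10-fold lower, MUM1L1 6.49-fold lower and GRHL3, an epithelial transcription factor, 6.46-fold lower (23.7 ± 3.16 CPM in ethanol and 3.68 ± 0.298 CPM in E2). B3GNT5, VTCN1 and COLEC10 were 6.14-fold, 5.59-fold and 5.52-fold lower. HCAR2 was 8.63-fold lower, but it is nearly identical to its neighbour HCAR3, so its counts are uncertain. edgeR adjusted p-values of these genes ranged from 9.83e-09 (GRHL3) to 5.34e-05 (B3GNT5).

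**Figure D1:**
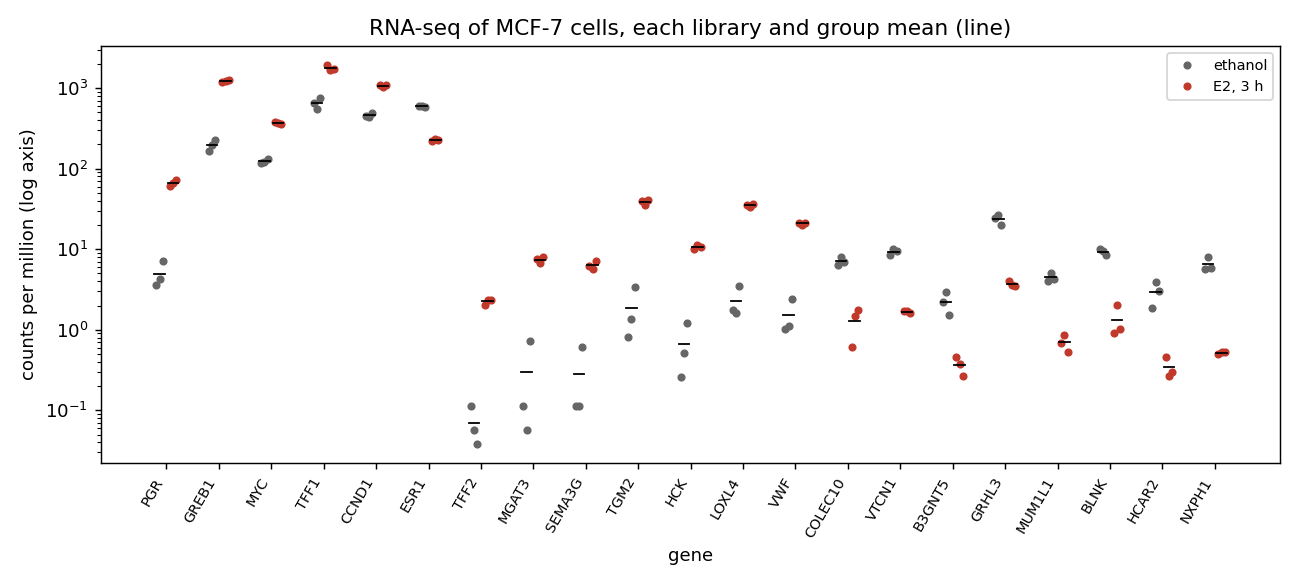
CPM (log axis) of named genes in each RNA library, 3 ethanol (grey) and 3 E2 at 3 h (red), with a line at each group mean, CYP24A1 being left out because a library had no counts. For every gene drawn the E2 libraries lie on 1 side of the ethanol libraries, from TGM2 at 1.86 and 38.3 CPM to NXPH1 at 6.53 and 0.520 CPM.

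Of 13671 genes, 2987 rose and 2717 fell at an edgeR adjusted p under 0.05 (41.7%). At least 2-fold, 466 rose and 328 fell. The groups did not overlap in 7120 genes (52.1%), where 10% would occur by chance with 3 against 3. With library size as the only scaling, 40.2% of the 6043 called genes rose in place of 52.4%. The authors' deposited table called 6032 genes, 3122 raised and 2910 lowered, and 5697 were shared. In the ethanol library replicate 3, 40 genes raised at least 8-fold stood at a median of 7.20% of the E2 change (95% interval 6.26 to 7.87%). The genes were chosen without the library in question. For ethanol replicates 1 and 2 this gave 26 and 25 genes, at -3.37% and -2.30%. The reference of these values includes replicate 3, so a shift of replicate 3 would by itself lower them. Without ethanol replicate 3, 2779 genes rose and 2432 fell.

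Genes described as estradiol-induced rose almost as a whole. Of 39 measured, 38 rose, also when adjusted over the list alone. They included RET, a receptor kinase (8.04-fold), IGFBP4, an IGF-binding protein (7.54-fold), CA12, a carbonic anhydrase (5.18-fold), and PDZK1, a scaffold protein (4.77-fold), while IGF1R, the IGF receptor, had a log2 fold change of -0.00 ± 0.06. Of 20 genes described as estradiol-repressed, 19 fell, also adjusted over the list alone. Among them were TGFB2, a growth factor (-2.25 ± 0.11), BMF, a pro-apoptotic BCL2 protein (-2.09 ± 0.09), TP53INP1 (-1.78 ± 0.07) and EFNA1, an ephrin (-1.14 ± 0.05), while PDCD4 rose slightly (0.20 ± 0.07). The camera adjusted p over lists was 5.28e-96 for the induced and 1.48e-26 for the repressed list, and 0.0218 and 0.0183 with an estimated correlation. Both lists come from earlier descriptions and not from these libraries.

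Most genes of ribosome biogenesis and of the G1/S transition rose. In ribosome biogenesis, 26 of 28 rose (27 adjusted over the list alone), among them DKC1 (1.89-fold), MYBBP1A (2.05-fold) and NOP16 (1.97-fold), which act in the nucleolus. Its camera adjusted p was 9.73e-24, and 0.0173 with an estimated correlation. In G1/S and replication, 22 of 30 rose, among them CCND1, CDCA7 (2.39-fold) and UHRF1 (1.74-fold). Adjusted over the list alone, 23 rose and 1 fell. For this list the camera adjusted p was 2.04e-08, and 0.261 with an estimated correlation. In G2/M and mitosis, 11 of 24 fell, also adjusted over the list alone, each by a small amount, such as BUB1 (-0.34 ± 0.06), NUSAP1 (-0.39 ± 0.08) and KIF20A (-0.28 ± 0.06). That list was not called (camera adjusted p 0.0575, and 0.494 with an estimated correlation), but it was called without ethanol replicate 1 (0.0396), without ethanol replicate 3 (0.0462), and with library size only (0.0354).

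In the stress and amino acid list, 11 of 23 rose and 2 fell, also adjusted over the list alone. SLC7A5 and SLC3A2, the chains of a leucine transporter, rose 6.10-fold and 2.96-fold, and XBP1, a transcription factor of the unfolded protein response, rose 2.47-fold. The chaperone HSPA5 and the stress gene DDIT3 did not pass (0.03 ± 0.05 and 0.15 ± 0.09). By camera the adjusted p was 8.76e-05, and 0.261 with an estimated correlation. In hypoxia and glycolysis, 11 of 17 rose (12 adjusted over the list alone) and 2 fell. The glucose transporter SLC2A1 rose 2.41-fold and hexokinase HK2 2.29-fold, while EGLN3, an oxygen-sensing hydroxylase, fell by 1.56 on the log2 scale. Here the camera adjusted p was 0.00011, and 0.262 with an estimated correlation. Of 24 immediate early genes, 12 rose and 3 fell, also adjusted over the list alone. EGR3 rose 6.94-fold and FOS 2.76-fold, BTG2, an antiproliferative gene, fell by 1.58, and EGR1 stood at 0.09 ± 0.07. For these genes the camera adjusted p was 0.00778, and 0.459 with an estimated correlation.

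Of 20 TGF-beta and BMP genes, 12 fell and 2 rose, also adjusted over the list alone, and the lowest p were those of TGFB2 (4.75-fold lower), TGFB3 (3.27-fold lower) and the signal transducer SMAD3 (1.70-fold lower). The camera adjusted p was 3.87e-06, and 0.111 with an estimated correlation. Genes of growth factor signalling went both ways, 8 up and 10 down of 26 (8 and 11 adjusted over the list alone). RET and IGFBP4 rose, while ERBB2 fell by 0.79 and EGFR fell by 0.46. The median was -0.10, the mean 0.20 and the camera direction up (adjusted p 0.65, and 0.0472 without ethanol replicate 3). Of 25 estrogen receptor cofactors, 7 rose and 9 fell, also adjusted over the list alone. NRIP1, a corepressor, rose 2.54-fold, and FOXA1, a factor that opens chromatin for the receptor, stood at -0.06 ± 0.06 (camera adjusted p 0.999, direction down with a mean of 0.06).

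Markers of other cells were looked at beside these groups. Of 11 basal and mesenchymal markers, 2 rose and 4 fell, also adjusted over the list alone, with CDH3, P-cadherin, lower by 1.80-fold, EGFR by 1.37-fold and KRT17, a basal keratin, by 1.48-fold (camera adjusted p 0.295). Of 9 fibroblast, endothelial and immune markers, 4 rose and 1 fell, also adjusted over the list alone. VWF rose, CDH5, a cadherin of endothelial cells, was 2.17-fold lower, and COL1A1, a fibroblast collagen, rose 2.26-fold, to 68.4 ± 12.2 CPM (log2 fold change 1.18 ± 0.37, edgeR adjusted p 0.0217). COL1A1 lost its call without E2 replicate 1 (edgeR adjusted p 0.0677), without E2 replicate 2 (0.0505) and in DESeq2 (0.134). The list had a camera adjusted p of 0.0523, and 0.55 with an estimated correlation. It was called with library size only (0.0221) and without ethanol replicate 1 (0.0311), 2 (0.045) or 3 (0.00088) or E2 replicate 3 (0.0278).

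Of 13 reference genes, 5 rose and 1 fell (2 adjusted over the list alone), with TFRC, the transferrin receptor, at 2.01-fold, HPRT1 at 1.29-fold and PGK1 at 1.18-fold (camera adjusted p 0.267). Of 11 core histone genes, 4 fell, among them HIST1H2AC (-0.50 ± 0.07), HIST2H2BE (-0.37 ± 0.06) and HIST1H2BD (-0.41 ± 0.08) (5 fell and 1 rose adjusted over the list alone, camera adjusted p 0.108), and near-identical copies leave their counts uncertain. Of 21 sterol and lipid genes, 6 rose and 3 fell, also adjusted over the list alone, with DHCR7 at 0.75 ± 0.06, ELOVL6 at 0.55 ± 0.09 and DHCR24 at -0.48 ± 0.05 (camera adjusted p 0.549). Of 13 interferon genes, 2 rose (HERC5, 3.78-fold, and IFIH1, 1.46-fold) and 2 fell (OAS3 and IRF9, by 0.39 and 0.66), also adjusted over the list alone (camera adjusted p 0.996). IGF1R, PDCD4, HSPA5, DDIT3, FOS, EGR1, FOXA1 and IRF9 lie outside the naming rule and were named after their values were seen. Genes of the mitochondrial genome had no measured members and were not analysed here. Of the 20 tested lists, 8 were called with the preset correlation and 3 with an estimated correlation.

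**Figure D2:**
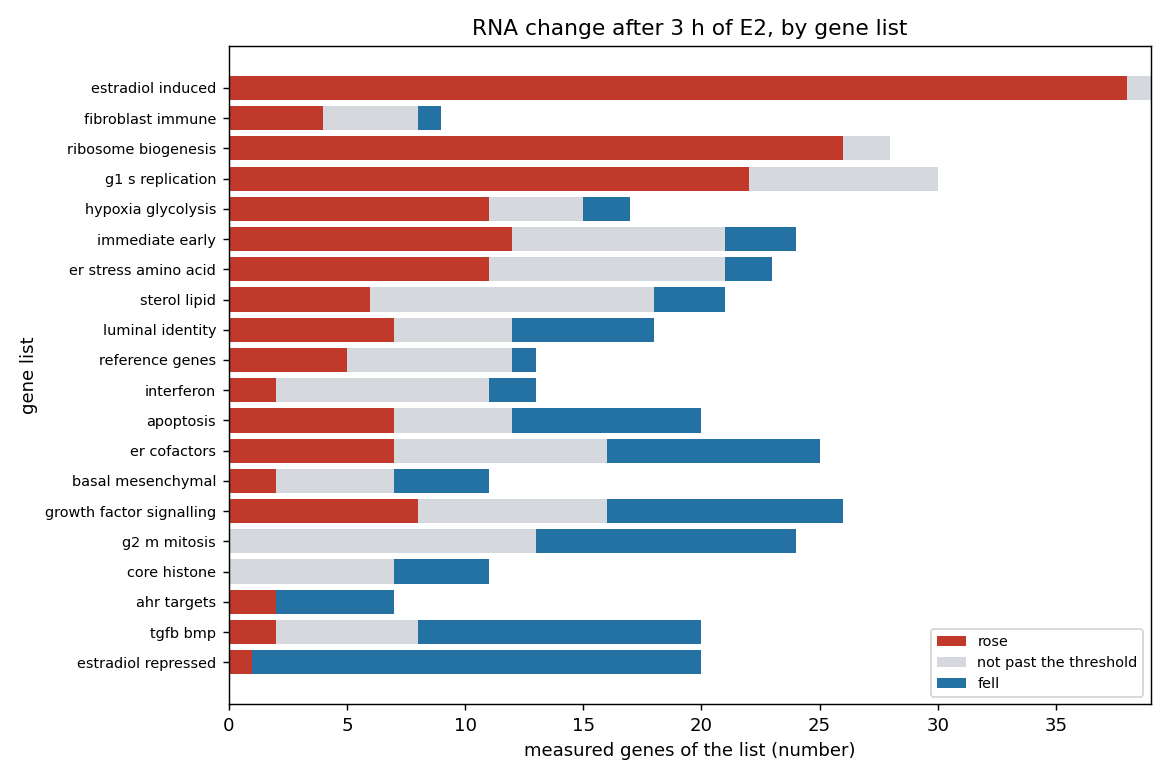
Number of measured genes (x axis) of each of the 20 tested lists (y axis, ordered by median log2 fold change) that rose (red), did not pass the threshold (grey) or fell (blue) after 3 h of E2. The estradiol-induced list has 38 of 39 genes raised and the estradiol-repressed list 19 of 20 lowered.

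At 1 h of E2, ATAC-seq showed single regions that opened or closed several-fold. A region in an intron of PDLIM3, which encodes a LIM-domain protein, at chromosome 4, 186431951 to 186432337, 24.4 kb from the 5' end, rose from 0.474 ± 0.0876 to 1.98 ± 0.712 CPM (log2 fold change 2.08 ± 0.35, edgeR adjusted p 0.000382). PDLIM3 RNA rose 8.09-fold at 3 h. Intron regions of SIMC1 (chromosome 5, 175742493 to 175743435) and of RAI1 (chromosome 17, 17658982 to 17659240, assigned to RAI1-AS1) rose by 2.09 ± 0.34 and 2.00 ± 0.36, and one in C16orf45 (chromosome 16, 15581640 to 15581962) by 1.88 ± 0.33 (edgeR adjusted p 0.000291, 0.00103 and 0.000787). A region outside the tabulated genes at chromosome 10, 9103599 to 9104559, assigned to LOC101928272, was 2.97-fold lower (-1.57 ± 0.21, edgeR adjusted p 3.51e-06), and one in an intron of the kinase gene MAP2K4 (chromosome 17, 11941203 to 11941867) fell by 1.80 on the log2 scale (edgeR adjusted p 0.00103).

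Regions near E2 targets were chosen by their p at 3 h, and those above by the size of their change at 1 h. Their sizes at 1 h are therefore not compared. The region 2.70 kb upstream of the 5' end of GREB1 (chromosome 2, 11670986 to 11671546) rose from 6.46 ± 2.39 to 12.4 ± 1.36 CPM (0.94 ± 0.21, edgeR adjusted p 0.0115), and of the 19 regions assigned to GREB1, 5 rose and 1 fell. The call of the GREB1 region was lost without ethanol replicate 3 (edgeR adjusted p 0.108) and without 1 h replicate 2 (0.0518). A region over an exon of PGR, 95.3 kb from its 5' end (chromosome 11, 100904760 to 100905261), rose by 0.87 ± 0.23 (edgeR adjusted p 0.0373) and lost its call without ethanol replicate 3 (0.186), 1 h replicate 2 (0.161) or 1 h replicate 3 (0.0749), when thinned (0.0714) and with only the 6 libraries compared (0.0571). The region 46.6 kb from CYP24A1 (chromosome 20, 52743626 to 52743872) rose by 0.88 ± 0.19 (edgeR adjusted p 0.01, and 0.0834 without ethanol replicate 3 and 0.0618 without 1 h replicate 2). Near SEMA3G (chromosome 3, 52466823 to 52467164) the change was 1.44 ± 0.35 (edgeR adjusted p 0.0246, and 0.068, 0.0697, 0.0973 and 0.0947 without ethanol replicate 2, ethanol replicate 3, 1 h replicate 2 and 1 h replicate 3). The region in MCF2L2, 38.2 kb from B3GNT5 (chromosome 3, 183009217 to 183009924), fell by 0.80 (edgeR adjusted p 0.0289, and 0.136, 0.0854 and 0.213 without ethanol replicate 3, 1 h replicate 2 and 1 h replicate 3, 0.0534 with offsets that follow accessibility, 0.0651 when thinned and 0.0572 with only the 6 libraries compared). The region 48.4 kb upstream of MUM1L1 (chromosome X, 105362723 to 105363929) fell by 0.71 (edgeR adjusted p 0.0489) and lost its call without ethanol replicate 2 (0.187) or 3 (0.135), 1 h replicate 2 (0.0652) or 3 (0.374) or 3 h replicate 1 (0.0585) or 2 (0.0715), with library size only (0.058), with offsets that follow accessibility (0.18) and with only the 6 libraries compared (0.0765). Of the 24 regions assigned to COLEC10, 2 fell, and of the 43 assigned to ESR1, 1 rose. The 2 regions of TFF1, 9 of CCND1 and 10 of MYC included no called region in edgeR.

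Other named regions of 1 h were less stable. Regions assigned to PDPN (chromosome 1, 13944950 to 13945572; 1.92 ± 0.37), LINC01592 (chromosome 8, 69847400 to 69847730; -1.64 ± 0.36), PRICKLE1 (chromosome 12, 42796758 to 42797152; -1.62 ± 0.40) and PTP4A1 (chromosome 6, 64168475 to 64168955; -1.58 ± 0.38) were called with all libraries. PDPN lost its call without 1 h replicate 3 (edgeR adjusted p 0.0893). LINC01592 lost its call without ethanol replicate 2 (0.0701) or 3 (0.0609). PRICKLE1 lost it without ethanol replicate 2 (0.053) or 3 (0.125) or 1 h replicate 2 (0.142) or 3 (0.22), with a log2 fold change of -2.46 without 1 h replicate 1, and PTP4A1 without ethanol replicate 2 (0.0644) or 3 (0.0645) or 1 h replicate 3 (0.256).

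Of 204297 regions, 1229 rose and 1231 fell at 1 h (1.20%), with a median log2 fold change of 1.02 among those that rose and -0.82 among those that fell. They lay over exons (469), in introns (708) or outside the tabulated genes (1283). Of the falls, 211 (17.1%) lay over the 5' end of a gene, where 5.08% of all regions lie, and 8 of the rises did. Over all 10372 such regions the median log2 fold change was -0.38, and -0.22 without ethanol replicate 2. They took 22.8 ± 2.50% of counts in ethanol and 18.6 ± 0.304% at 1 h (SD, n = 3). The share that rose depended on the scaling. It was 49.96% with TMM, 79.8% with library size only, 75.0% with offsets that follow mean accessibility and 44.8% with relative log expression factors. It also depended on the test, with 49.8% in limma-voom and 15.8% in DESeq2. The median log2 fold change over all regions was -0.0023 both in DESeq2 and with relative log expression factors. The authors' deposited table called 2567 regions, 1305 raised and 1262 lowered, and 2430 were shared. Leaving out a library moved the counts of rises and falls to 3047 and 5217 (ethanol replicate 1), 205 and 200 (ethanol replicate 2), 250 and 205 (ethanol replicate 3), 3394 and 2941 (1 h replicate 1), 483 and 467 (1 h replicate 2), 107 and 32 (1 h replicate 3) and 830 and 692 (3 h replicate 2).

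At 3 h of E2, falls outnumbered rises among called regions. A region 141 kb from the 5' end of PAWR, a pro-apoptotic gene (chromosome 12, 79943194 to 79943649), had 10.3 ± 1.65 CPM in ethanol, 3.81 ± 0.998 at 1 h and 3.30 ± 0.338 at 3 h (3 h log2 fold change -1.65 ± 0.22, edgeR adjusted p 1.94e-06). A region 32.0 kb from ERP27, a protein of the endoplasmic reticulum (chromosome 12, 15059007 to 15059490), fell from 4.73 ± 0.903 to 1.49 ± 0.162 CPM (-1.66 ± 0.25, edgeR adjusted p 3.88e-05). The one assigned to LOC339298 (chromosome 18, 73635109 to 73635539) fell by 1.80 (edgeR adjusted p 0.000265). Among the rises, the PDLIM3 intron region stayed at 1.84 ± 0.222 CPM (1.95 ± 0.35, edgeR adjusted p 0.00053), and a region assigned to LOC646736 (chromosome 2, 226707762 to 226708823) rose from 1.47 ± 0.443 to 4.73 ± 1.49 CPM (1.69 ± 0.26, edgeR adjusted p 3.88e-05). These calls held in every alternative and with each library left out.

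Near E2 targets at 3 h, the GREB1 upstream region stood at 12.3 ± 2.53 CPM (0.92 ± 0.21, edgeR adjusted p 0.0116, and 0.129 without ethanol replicate 3 and 0.132 without 3 h replicate 1), and 3 of the 19 GREB1 regions rose. The MUM1L1 upstream region fell from 25.2 ± 4.70 to 12.1 ± 1.96 CPM (-1.06 ± 0.20, edgeR adjusted p 0.00142), and MUM1L1 RNA fell too. A region in an intron of RPRD1B assigned to TGM2 (chromosome 20, 36712700 to 36713341) fell by 1.05 while TGM2 RNA rose. Its edgeR adjusted p was 0.0185, and 0.605 without ethanol replicate 2, 0.0955 without 3 h replicate 1 and 0.175 without 3 h replicate 3, and it was also past 0.05 with library size only, when thinned and in limma-voom. The PGR exon region stood at 0.78 ± 0.23 (edgeR adjusted p 0.0858), the SEMA3G region at 1.28 ± 0.36 (0.0618) and the CYP24A1 region at 0.54 ± 0.19 (0.178, but 0.00595 with offsets that follow accessibility and 0.0428 in DESeq2). Regions of lowest p had an edgeR adjusted p of 0.491 for TFF1, 0.35 for MYC, where the region covers the 5' end (chromosome 8, 128745978 to 128751082; -0.36 ± 0.17), 0.498 for CCND1 and 0.195 for ESR1. VTCN1 (-0.61 ± 0.19, edgeR adjusted p 0.113) and COLEC10 (-0.68 ± 0.21, 0.0945) were called without ethanol replicate 1 (0.0214 and 0.0235) and in DESeq2 (0.0344 and 0.0239). The region assigned to NXPH1, 452 kb from its 5' end (0.78 ± 0.25, 0.114), was called without ethanol replicate 1 (0.0295). TFF2, MGAT3, HCK, LOXL4, VWF, HCAR2, BLNK, GRHL3 and B3GNT5 had no region called by edgeR at 3 h with all libraries, while DESeq2 called the B3GNT5 region (adjusted p 0.028).

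Other large changes at 3 h kept their direction but not their call when a library was left out. The region in TTC27 assigned to MIR4765 (chromosome 2, 32942055 to 32942558; 2.33 ± 0.40) lost its call without 3 h replicate 3 (log2 fold change 1.91, edgeR adjusted p 0.0541). HYDIN (chromosome 16, 71131836 to 71132159; 1.69 ± 0.36) lost it without ethanol replicate 2 (0.146) or 3 h replicate 1 (0.0621). COG5 (chromosome 7, 106905908 to 106906301; 1.68 ± 0.39) lost it without ethanol replicate 2 (0.15), 3 h replicate 2 (0.0718) or 3 h replicate 3 (0.257). LINC00376 (chromosome 13, 63999294 to 63999630; -1.82 ± 0.38) lost it without 3 h replicate 1 (0.054) or 2 (0.0545), and CAVIN2 (chromosome 2, 192665660 to 192665973; -1.70 ± 0.36) without ethanol replicate 2 (0.123), 3 h replicate 2 (0.119) or 3 h replicate 3 (0.0544). With a library left out, the log2 fold changes lay between 1.91 and 2.61 for MIR4765, 1.39 and 1.95 for HYDIN, 1.43 and 1.94 for COG5, -2.22 and -1.64 for LINC00376, and -2.22 and -1.30 for CAVIN2.

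At 3 h, 271 regions rose and 1066 fell, with medians of 1.07 and -0.90 on the log2 scale. They lay over exons (90), in introns (459) or outside the tabulated genes (788), and 20 of the falls lay over 5' ends (1.88%). Over all 5' ends the median was -0.28, and -0.12 without ethanol replicate 2, and their share of counts was 19.6 ± 2.00%. The share of called regions that rose was 20.3% with TMM, 40.8% with library size only, 48.6% with offsets that follow accessibility, 17.8% with relative log expression factors, 23.6% in limma-voom and 9.09% in DESeq2. The authors' deposited table called 1440 regions, 297 raised and 1143 lowered, and 1332 were shared. Leaving out a library gave rises and falls of 688 and 3053 (ethanol replicate 1), 81 and 153 (ethanol replicate 2), 196 and 562 (ethanol replicate 3), 91 and 422 (3 h replicate 1), 135 and 268 (3 h replicate 2) and 64 and 149 (3 h replicate 3).

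**Figure D3:**
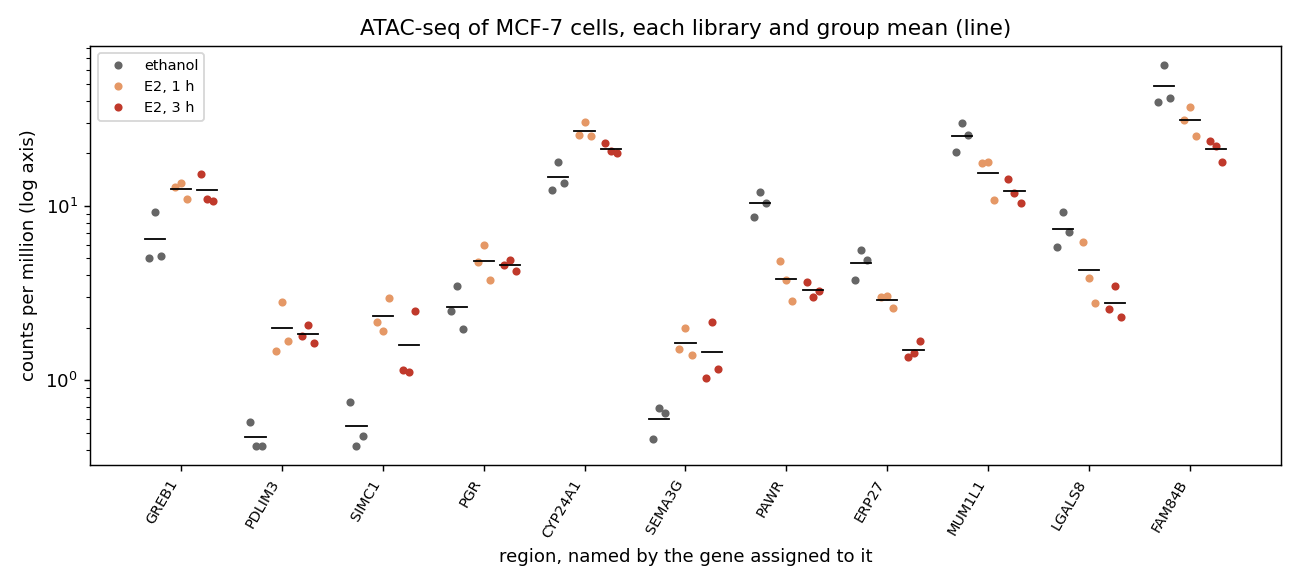
ATAC CPM (log axis) of named regions, each given the name of its assigned gene, in each ethanol (grey), 1 h (orange) and 3 h (red) library, with a line at each group mean of 3 libraries. The GREB1 region lies at 6.46, 12.4 and 12.3 CPM and the PAWR region at 10.3, 3.81 and 3.30 CPM.

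**Figure D4:**
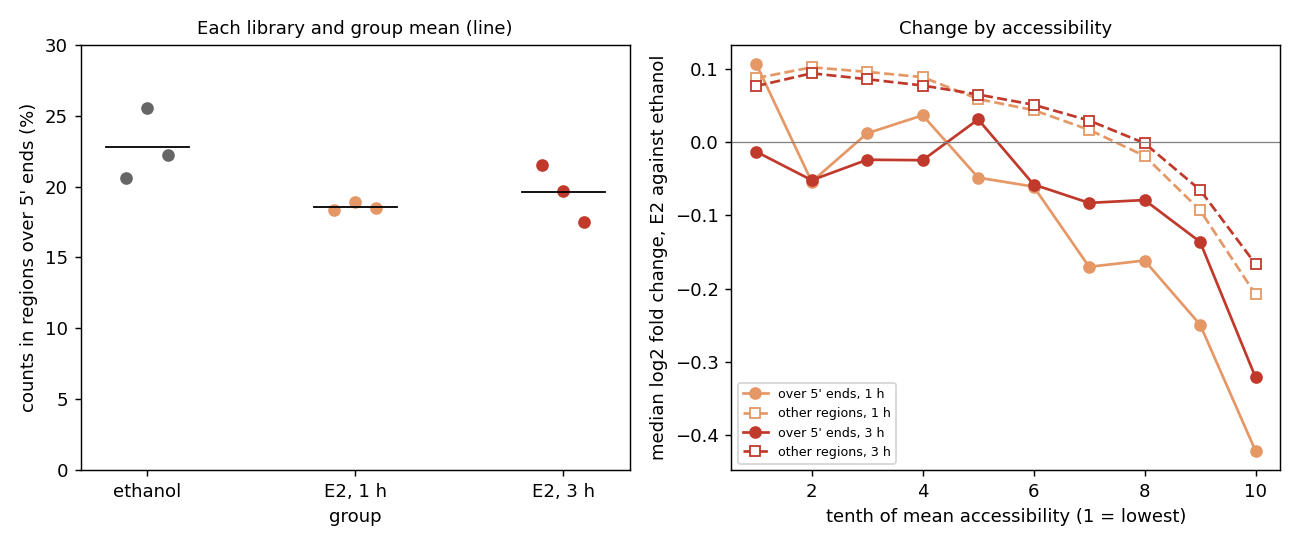
Left, percentage of ATAC counts in regions over 5' ends in each library with a line at the group mean; right, median log2 fold change against ethanol (y axis) in 10 bins of mean accessibility (x axis, 1 lowest) for regions over 5' ends (filled circles) and other regions (open squares) at 1 h and 3 h. Over all regions the medians go from 0.09 (1 h) and 0.08 (3 h) in the lowest bin to -0.33 and -0.25 in the highest, and the shares average 22.8% in ethanol, 18.6% at 1 h and 19.6% at 3 h.

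The test of 3 h directly against 1 h asked whether accessibility differed between the times. It found 3 regions higher and 8 lower at 3 h (edgeR; 12229 regions at an unadjusted p under 0.05), and DESeq2 found 1 and limma-voom 2. The region 16.6 kb from CNNM2, a magnesium transport gene (chromosome 10, 104661001 to 104661433), had 1.06 ± 0.0808 CPM in ethanol, 0.423 ± 0.0567 at 1 h and 2.01 ± 0.0507 at 3 h (2.25 ± 0.39, edgeR adjusted p 0.00348). Its call was lost without 1 h replicate 2 (0.0933), 1 h replicate 3 (0.0623) or 3 h replicate 1 (0.0531). CNNM2 RNA fell at 3 h (-0.89 ± 0.09). Leaving out a library gave 73 regions (1 h replicate 1) and 24 regions (3 h replicate 2), while no region was called by edgeR without 1 h replicate 2, 1 h replicate 3 or 3 h replicate 1.

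Of the regions called up, 89 were shared between the times, and of those called down 344. Independent lists of these sizes would share 1.63 and 6.42, a value that leaves out the shared ethanol libraries. In 10 simulations of unchanged groups with shared controls edgeR called 0 regions, so the simulated overlap was 0, a value that leaves out the real changes. The log2 fold changes had a Pearson correlation of 0.658 across 204297 regions, against 0.463 (0.460 to 0.466) in these simulations. The covariance was 0.0846, against 0.0345 simulated, a difference of 0.0501. With 3 ethanol libraries the controls could not be split into parts of 2, so part of the excess in overlap and correlation may come from the shared controls. At the simulated spread, shared controls add the same covariance with or without real changes. The simulations drew each region independently and at a common spread for all groups, without the trend with accessibility seen at both times. The difference in covariance can therefore also hold such a trend or a wider spread of the ethanol libraries, and does not isolate a response to E2.

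Regions assigned to the gene lists shifted little. At 1 h, 6 of 20 lists had lower accessibility by camera with the preset correlation, among them G2/M (124 regions, 3 fell, adjusted p 0.0252), apoptosis (110 regions, 2 rose and 1 fell, 0.0252) and core histones (29 regions, 1 rose, 0.0392). At 3 h, 6 lists did, among them estradiol-repressed genes (163 regions, 3 fell, 11 adjusted over the list alone, camera adjusted p 0.00605), hypoxia and glycolysis (0.0142) and sterol and lipid genes (0.00605). With offsets that follow accessibility the calls of core histones (0.309), estradiol-repressed (0.0744) and sterol and lipid genes (0.0749) at 1 h and of hypoxia and glycolysis and G2/M (0.0713 each) at 3 h were lost. The interferon list (0.0471, lower) was called at 1 h, and estrogen receptor cofactors and reference genes were called up at 1 h (0.0471 each). With an estimated correlation none of the lists was called, with lowest adjusted p of 0.747 at 1 h and 0.817 at 3 h. Of the 391 regions of estradiol-induced genes, 9 rose and 3 fell at 1 h (22 and 16 adjusted over the list alone; camera adjusted p 0.367), and 5 rose and 3 fell at 3 h (10 and 8 adjusted over the list alone; 0.654).

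The series title names the relation of the assays. Among the 12338 genes with an assigned region, most raised or lowered genes had no region called by edgeR at either time. This held for 2387 of 2715 raised genes (87.9%) and 2041 of 2537 lowered genes (80.4%), beside 90.2% of uncalled genes. These shares depend on the assignment. With the nearest strand-aware 5' end, 10.1% of raised genes had a region called up at 1 h in place of 6.74% (uncalled genes 6.46% in place of 3.91%). A region called down was then found at 14.6% of lowered genes in place of 10.4% (uncalled genes 6.17% in place of 3.94%). The share without any called region was not taken with that assignment. With the authors' assignment, the share without a called region was 80.1% (351 of 438) among genes raised at least 2-fold. It was 68.5% (207 of 302) among those lowered at least 2-fold. The median number of assigned regions was 6 and 8 in these classes, 4 for raised, 5 for lowered and 3 for uncalled genes. These shares were not matched for the number of regions. TFF1, MYC and CCND1 had no called region, and GREB1, PGR, SEMA3G and PDLIM3 had at least 1. A region that was not called is not shown to be unchanged. In the simulation the ATAC test of 3 h recovered 2.99% of 1.5-fold and 38.8% of 2-fold changes, and calls moved widely when a library was left out. The regions of lowest p at 3 h among RNA-called genes included, besides PAWR and ERP27, those of LGALS8, a galectin (chromosome 1, 236670518 to 236671049; -1.40 ± 0.23), FAM84B, 21.2 kb upstream (chromosome 8, 127591947 to 127593113; -1.20 ± 0.20), and FAM181B (chromosome 11, 82391140 to 82391730; -1.30 ± 0.22). RNA of these genes fell by 1.04, 0.52 and 1.55. RNA of PAWR fell by 0.42 and of ERP27 by 0.91. Regions of MID1IP1 (chromosome X, 38871016 to 38872562; -1.28 ± 0.21) and METAP1 (chromosome 4, 99897824 to 99898465; -1.32 ± 0.22) fell while their RNA rose (0.26 ± 0.08 and 0.20 ± 0.06). The region of DSCAM-AS1 in DSCAM (chromosome 21, 41696288 to 41697118) rose by 1.41 ± 0.24 and its RNA by 0.39 ± 0.07, which is uncertain for an antisense gene because the strand setting is not given. All 8 regions had an edgeR adjusted p of 0.000256 or lower, and their calls held with each library left out.

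Lowered genes more often had a region that closed. At 3 h, 208 of 2537 lowered genes (8.20%) had a region called down, against 219 of 7086 uncalled genes (3.09%), an odds ratio of 2.80 (2.29 to 3.42; Fisher's exact p 4.86e-24). Labels shuffled among lowered and uncalled genes of like expression and number of regions gave a mean of 5.71%, which includes the lowered genes themselves. The permutation p was 2e-05, the smallest that the resamples can give. Among genes lowered at least 2-fold, 16.2% had a region called down. These genes had a median of 8 assigned regions, against 5 for all lowered and 3 for uncalled genes, and no matched test was run on them. At 1 h the shares were 10.4% of lowered and 3.94% of uncalled genes (odds ratio 2.82, Fisher's exact p 7.01e-30). The odds ratio exceeded 2 and the matched permutation p stayed at or under 0.0002 with each library left out, while the number of lowered genes with such a region became 491, 44 and 115 without ethanol replicates 1, 2 and 3 and 93, 59 and 41 without 3 h replicates 1, 2 and 3. Without ethanol replicate 2 the odds ratio was 4.79.

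Raised genes more often had a region that opened, but less firmly. At 3 h, 56 of 2715 raised genes (2.06%) had a region called up, against 48 of 7086 uncalled genes (0.677%). The odds ratio was 3.09 (2.06 to 4.65, Fisher's exact p 2.59e-08). Labels shuffled among matched raised and uncalled genes gave a mean of 1.23% (permutation p 6e-05). The call was lost without ethanol replicate 3 (odds ratio 1.37, exact p 0.22, matched permutation p 0.75) and without 3 h replicate 1 (1.65, 0.127 and 0.26). Without ethanol replicate 1 the exact p was 0.0342 and the matched permutation p 0.45 (odds ratio 1.34), and the odds ratio was 9.51 without ethanol replicate 2 and 6.72 without 3 h replicate 3. The number of raised genes with such a region became 87, 36 and 23 without ethanol replicates 1, 2 and 3 and 17, 27 and 23 without 3 h replicates 1, 2 and 3. At 1 h, 183 raised genes (6.74%) had a region called up, against 277 uncalled genes (3.91%; odds ratio 1.78, Fisher's exact p 9.45e-09, matched permutation p 4e-05).

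Opposite pairings were also counted. A region called down was found at 2.51% of raised genes (odds ratio 0.806, Fisher's exact p 0.141). The matched permutation p was 0.028, and 0.24, 0.24 and 0.28 without ATAC ethanol replicates 1, 2 and 3, 0.45, 0.68 and 0.4 without 3 h replicates 1, 2 and 3, 0.081 and 0.17 without RNA ethanol replicates 1 and 2, and 0.1 without RNA E2 replicate 2. A region called up was found at 1.89% of lowered genes (odds ratio 2.83, Fisher's exact p 9.5e-07). Its matched permutation p was 0.0061, and 0.99, 0.47 and 0.7 without ATAC ethanol replicates 1, 2 and 3, 1, 0.23 and 1 without 3 h replicates 1, 2 and 3, and 0.095 without RNA ethanol replicate 2. Its odds ratio was 0.838 without ATAC ethanol replicate 2.

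**Figure D5:**
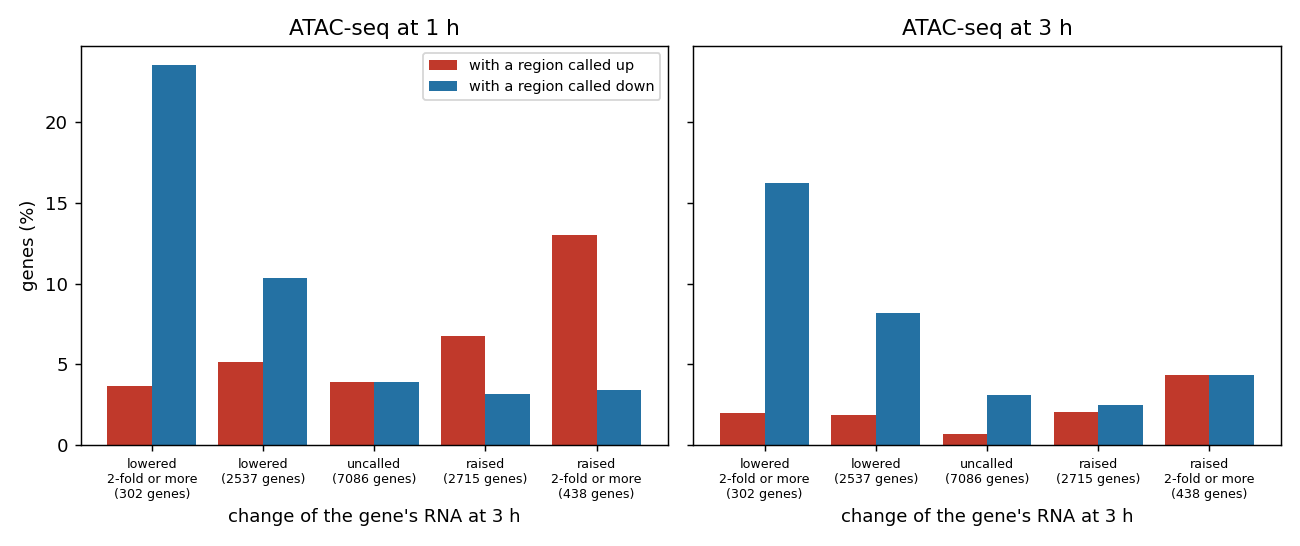
Percentage of genes (y axis) with at least 1 assigned region called up (red) or called down (blue) at 1 h (left) and 3 h (right), by the change of the gene's RNA at 3 h. Among genes lowered at least 2-fold, 23.5% at 1 h and 16.2% at 3 h had a region called down, and among genes raised at least 2-fold 13.0% and 4.34% had a region called up. The shares are not matched for the number of assigned regions, whose median was 8 and 6 in these classes and 3 in uncalled genes.

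Across 12338 genes, the RNA log2 fold change and that of the most accessible assigned region at 3 h had a Spearman correlation of 0.113 (bootstrap interval 0.0950 to 0.131) and a Pearson correlation of 0.126. Over the 5252 genes called in RNA the Spearman correlation was 0.170 (0.144 to 0.197). With the mean over assigned regions it was 0.0646, and at 1 h 0.126. The regions of all raised genes, or of all lowered genes, as a set were not called by camera at 3 h (adjusted p 0.953 and 0.928) or at 1 h (0.57 and 0.479).

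Accessibility before E2 was compared at the 5' ends of the gene classes. In the 3 ethanol ATAC libraries, 5' end regions of 2592 raised genes lay -0.04 ± 0.01 (SD, n = 3) from expression-matched uncalled genes on the log2 scale, and those of 2337 lowered genes 0.04 ± 0.02. The permutation p was 0.26, 0.037 and 0.21 in ethanol replicates 1, 2 and 3 for raised genes and 0.013, 0.28 and 0.1 for lowered genes, so neither difference passed in every library. Without matching, the difference of lowered genes was 0.09 ± 0.01 and passed in every library (largest permutation p 0.0045). Over all assigned regions it was -0.12 ± 0.02 for lowered genes (largest permutation p 1e-05) and -0.05 ± 0.01 for raised genes (0.015), so direction and call depend on the regions and the matching used.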

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

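Both tests of mixed RNA in ethanol replicate 3, the comparison of ATAC depths, the test on thinned libraries and the alternatives with offsets that follow accessibility, thinning or strand-aware assignment were chosen after the result was seen. The results of 3 h against 1 h are given here because a direct test of the difference between the times called them.

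In the test of 3 h against 1 h, 3 regions were higher and 8 lower at 3 h. The higher ones were assigned to CNNM2 (2.25), NUP160 (chromosome 11, 47874968 to 47875424, 1.55) and GPATCH2 (chromosome 1, 217292627 to 217293473, 1.13). Values are log2 fold changes of 3 h against 1 h. These regions lay 16.6 kb, 4.91 kb and 511 kb from the 5' ends. The largest falls were assigned to TP53TG3B (chromosome 16, 33237503 to 33238150, -1.84), CYTOR (chromosome 2, 87623676 to 87624046, -1.78) and CUL2 (chromosome 10, 35310511 to 35310780, -1.55). The CUL2 region lay in that gene, and no distance could be given for TP53TG3B and CYTOR. In DESeq2 the adjusted p was 0.182 for NUP160 and GPATCH2, 0.814 for TP53TG3B, 0.771 for CYTOR and 0.865 for CUL2. Over all alternatives, DESeq2 and limma-voom included, the adjusted p ranged from 0.0012 to 0.0933 for CNNM2 and from 3.33e-07 to 0.771 for CYTOR. Counts in the CYTOR region were 33, 201 and 129 in 1 h replicates 1, 2 and 3, so replicate 1 lay far below the others, and its call was lost without replicate 2 (edgeR adjusted p 0.186) or 3 (0.164). Of the 10 splits of these libraries, 2 gave 11 or more regions, the highest other split giving 25. No biological explanation of these regions was tested.

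Regions over 5' ends had a lower median in both E2 groups, -0.38 at 1 h and -0.28 at 3 h. With libraries thinned to the smallest total the medians were -0.374 and -0.269. Thinning keeps each library's proportions, so it could hardly move these medians and cannot decide whether the number of counts plays a part. ATAC depth and library properties that go with it cannot be told apart from the pattern. The deepest E2 library, at 26.6 M counts, lies under the lowest ethanol library, at 34.6 M. Ethanol replicate 2 alone was not settled as the source at 3 h. Without it the median was -0.118, past the bound of -0.1 by less than the spread of 0.103 between leave-one-out values. At 1 h the median without it was -0.219. Ethanol replicates 1 and 3 held 20.6% and 22.3% of counts over 5' ends, above every 1 h library (18.3 to 18.9%). These values argue against ethanol replicate 2 alone as the source at 1 h. At 3 h the libraries overlapped with ethanol. Replicates 1, 2 and 3 of 3 h held 21.5%, 19.7% and 17.5%, and the first of these lay above ethanol replicate 1. A trend with accessibility in all regions was not settled either. Within the 10 bins the 5' ends lay -0.134 from other regions at 3 h, with a leave-one-out spread of 0.0521. At 1 h they lay -0.196 from other regions, a value for which no such spread was taken. Offsets that follow accessibility reduced the medians to -0.138 at 1 h and -0.0821 at 3 h. A closing of 5' ends by E2 stays open and was not tested apart from these.

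The RNA library ethanol replicate 3 lay nearer to the E2 libraries than the other ethanol libraries. Mixed-in RNA or reads of E2 libraries would put all E2-regulated genes at an equal fraction of the E2 change. With genes and levels from the same libraries, the genes lowered at least 2-fold stood at 12.2% (9.32 to 14.2) and those raised at least 8-fold at 7.20% (6.26 to 7.87), which decides nothing because the genes were chosen on these libraries. With genes chosen and levels taken in separate libraries the fractions were 9.22% (6.81 to 11.03) and 6.47% (5.46 to 7.35), so mixing fits. Near-equal fractions are not specific to mixing: replicates 1 and 2, whose references include replicate 3, also had overlapping intervals (medians of raised and lowered genes -6.91% and -4.84%, and -5.89% and -7.38%), and a weak hormone response in the culture of replicate 3 might give them too and was not tested.

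Raised genes more often had a region called up at 3 h. The strand-blind assignment is argued against as its cause, since with the nearest strand-aware 5' end the lower end of the odds ratio's interval was 1.87, and from 1.24 to 4.07 with a library left out where the pattern was called. It was 0.943 without ethanol replicate 3 and 1.1 without 3 h replicate 1, where the authors' assignment gave 0.787 and 0.841 and no call either. A greater number of regions or a higher expression of raised genes cannot be told apart from it: the matched permutation p of 6e-05 met the bound written beforehand, but without ethanol replicate 1 the exact p was 0.0342 while the matched permutation p was 0.45, so that bound did not hold up against the spread between libraries. With all libraries lowered genes showed nearly the same excess, 1.89% with a region called up (odds ratio 2.83) beside 2.06% of raised genes (3.09). Without ethanol replicate 2 the odds ratios were 0.838 for lowered and 9.51 for raised genes. Opening of chromatin by E2 stays open as a hypothesis.

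Splits of the 6 libraries of a contrast into other groups of 3 gave these counts, each out of 10 splits including the real one. For RNA genes, 1 split reached the real 5704, and no other split gave a called gene in edgeR. For regions at 1 h, 1 split reached 2460 and the highest other gave 3, and at 3 h 1 split reached 1337 and no other gave a called region in edgeR. For lists, 5 splits reached the 8 RNA lists (highest other 11), 4 splits the 6 ATAC lists at 1 h and 6 splits the 6 lists at 3 h (highest other 13 at both times). The preset correlation of camera therefore called as many lists in other groupings. Every other split puts ethanol and E2 libraries in both groups, unequally, so part of the E2 difference stays between them. The rest widens the spread within groups, so a real E2 effect would by itself lower the counts of genes and regions there. Lists called in these splits may come from E2, so the counts cannot decide whether the calls of lists reflect E2.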

How the results depend on the processing

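Offsets that follow accessibility, thinning, strand-aware assignment, plus-strand genes, the settings at 1 h that join a pair of choices, and limma-voom and thinning for 3 h against 1 h were chosen after the result was seen. Values are calls unless named otherwise, with rises and falls in this order; the cause of a difference was not tested.

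An adjusted p under 0.01 gave 1737 RNA falls, 260 regions at 1 h (133 and 127) and 324 at 3 h (49 and 275). An adjusted p under 0.2 gave 25875 at 1 h (12315 and 13560) and 9293 at 3 h (3159 and 6134). A fold of 1.5 or more gave 1970 RNA genes (1077 and 893). With library size only there were 3780 regions at 1 h (3015 and 765), and 412 and 598 at 3 h. With offsets that follow accessibility there were 2060 and 686 at 1 h, 642 and 680 at 3 h, and 4 for 3 h against 1 h (1 and 3). Thinned to the smallest total, 759 rose at 1 h, and 3 h against 1 h gave 7, of which 4 fell. With only the 6 libraries compared there were 1160 at 1 h (640 and 520). DESeq2 gave 7570 at 1 h (6378 falls), 3401 at 3 h (3092 falls) and 1 for 3 h against 1 h, which rose, with no falls. Relative log expression factors gave 5 falls for 3 h against 1 h, and limma-voom 2 calls (1 and 1). With an estimated correlation, 3 RNA lists were called and 0 ATAC lists at 1 h and 0 at 3 h.

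The replicate number as a block gave 6421 regions at 1 h (2832 and 3589), 2446 at 3 h (600 and 1846), 30 for 3 h against 1 h (14 and 16) and 7028 RNA genes. The labels do not say that equal numbers were made together. Libraries of the same number correlated, after removal of group means, at -0.061 to 0.186 in RNA, -0.133 to 0.235 for ethanol with 1 h, -0.154 to 0.148 for ethanol with 3 h and -0.0475 to 0.0492 for 1 h with 3 h, where other numbers reached 0.167, 0.13, 0.181 and 0.159. Not every library correlated best with its own number and the minimum of 0.1 was not met, so the block was not used. With it the PGR region at 3 h was called (edgeR adjusted p 0.0362), as was the G2/M list in RNA (camera adjusted p 0.0431). The matched permutation p was 0.059 for raised genes with a region called down and 0.43 for lowered genes with one called up.

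For raised genes with a region called up, the matched permutation p was 0.082 with regions at an adjusted p under 0.2 and 0.33 at an unadjusted p under 0.05. For raised genes with a region called down, the odds ratio was 0.853 (adjusted p under 0.2, now past the threshold), 1.02 (RNA fold of 1.5 or more, reversed) and 0.823 (strand-aware at 1 h, now past the threshold). Its matched permutation p was 0.16 (RNA fold of 1.5 or more), 0.46 (regions within 10 kb), 0.51 (within 100 kb), 0.24 (strand-aware), 0.23 (plus-strand genes), 0.24 (offsets that follow accessibility) and 0.12 (these offsets at 1 h). For lowered genes with a region called up, the odds ratio was 1.79 (RNA fold of 1.5 or more) and 2.08 (within 10 kb). Its matched permutation p was 0.78 (adjusted p under 0.2), 0.041 (unadjusted p under 0.05, reversed), 1 (RNA fold of 1.5 or more), 0.39 (within 10 kb), 0.28 (within 100 kb), 0.18 (strand-aware), 0.64 (strand-aware at 1 h), 1 (offsets), 0.17 (offsets at 1 h) and 0.43 (at 1 h).

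The Spearman correlation of the assays was 0.0646 with the mean over assigned regions, 0.132 with strand-aware assignment and 0.145 with that at 1 h. Basal differences at 5' ends without matching were 0.000133 (raised, reversed) and 0.0862 (lowered, now past the threshold), and over all assigned regions -0.0546 (raised, now past the threshold) and -0.123 (lowered, reversed). At a mean CPM of 1 or more the correlation between 1 h and 3 h changes was 0.661.

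Leaving out each library gave 139 to 8264 regions at 1 h (107 to 3394 and 32 to 5217), 213 to 3741 at 3 h (64 to 688 and 149 to 3053) and 0 to 73 for 3 h against 1 h (0 to 44 and 0 to 29). For raised genes with a region called up, the odds ratio ranged from 1.34 to 9.51 and the matched permutation p from 2e-05 to 0.75. For raised genes with one called down the p ranged from 0.025 to 0.68. For lowered genes with one called up, the odds ratio ranged from 0.838 (reversed) to 3.03 and the p from 0.0018 to 1. RNA counts, the number of RNA lists (8 to 11) and lowered genes with a region called down (odds ratio 2.35 to 4.79, matched permutation p 2e-05 to 0.0002) kept their calls.

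Among single results, 164 of 180 values of RNA lists, 933 of 936 of named RNA genes and 1136 of 1280 of named regions kept their call or stayed uncalled. No log2 fold change of a named gene or region changed sign. For lists no direction was reversed where the main or the alternative value was called. Where a list was uncalled in both, its direction was not compared. The alternative without a filter removed nothing and is void, a pseudocount did not apply to counts, and motif content was not run. In the simulation the ATAC test found 2.99% of changes of 1.5-fold, at 1 setting of depth, number of libraries, spread and number of changed regions. Which of these limits the region tests was not tested.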

Other observations

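All genes were named here by the rule fixed beforehand except PMAIP1, BCL2, GATA3, KRT8, AHR, ARNT and AHRR, which were chosen after the result was seen.

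Luminal identity genes went both ways after 3 h of E2. Of 18, 7 rose and 6 fell (8 and 7 adjusted over the list alone), with the keratins KRT19 (0.87) and KRT8 (0.72) and the transcription factor XBP1 (1.31) higher on the log2 scale and ESR1 (-1.37) and GATA3, a luminal transcription factor (-0.50), lower. The camera adjusted p of the list was 0.637. Of 20 apoptosis genes, 7 rose and 8 fell (7 and 9 adjusted over the list alone). The pro-apoptotic BMF (-2.09), TP53INP1 (-1.78) and BIK (-1.32) fell, while the anti-apoptotic BCL2 (1.44) and the pro-apoptotic PMAIP1 (1.98) rose. The camera adjusted p was 0.0774, and 0.045 without ethanol replicate 2, over a range of 0.045 to 0.261.

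All 7 measured genes of the list for the aryl hydrocarbon receptor, a sensor of foreign compounds, changed, 2 up and 5 down, the receptor gene and its partner ARNT included, also adjusted over the list alone. TIPARP, an ADP-ribosyltransferase, rose 3.65-fold and the cytochrome CYP1B1 rose by 0.86 on the log2 scale. The cytochrome CYP1A1 was 3.77-fold lower, and the receptor gene AHR (-0.43) and its repressor AHRR (-0.32) fell. The camera adjusted p was 0.65.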
